A study of Escherichia coli K-12 with 15 samples.

How the data were processed

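RNA from Escherichia coli K-12 W3110 was measured on 15 Affymetrix antisense arrays, with 5 arrays for each growth pH (5.0, 7.0 or 8.7). Per the labels, every array carried biotin-labelled cDNA from its own culture, in potassium-modified LB (LBK) with 50 mM HOMOPIPES, shaken at 240 rpm at 37°C and harvested at an OD600 of 0.3 with RNAprotect and the RNeasy kit. The deposited values are linear signal intensities, 1 per probe set and array, and GCOS is the tool named in the submitters' processing notes. Its version is not given in the sources used here. On every array the mean without the lowest and highest 2% of the deposited signal intensities lay between 1000.4 and 1000.6, so the arrays had been scaled to a common target. The series text says that the authors' own analysis used dChip expression indices with pH 7 replicate 1 as the reference, and tested them by analysis of variance and Tukey's test. The deposited intensities were not shown to be those indices, and they were analysed as signals. Instrument records of the 15 arrays gave the chip lot, the fluidics protocol and the scan day, which were used only to define technical batches.

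The 7312 probe sets held 4345 for genes, 2886 for intergenic regions, 22 array controls and 59 for phage and plasmid sequences used as a background. Genes took the symbols of the MG1655 reference annotation (build ASM584v2) through the locus tag for 4142 probe sets, the gene identifier for 90 and the probe set identifier for 72, and 41 probe sets with several genes were left unnamed. The annotation served for names and gene order only, and 126 gene probe sets whose probes are shared between genes were marked. The array medians of log2 signal spanned 0.68, above a limit of 0.3 set before the data were examined, so the arrays were quantile-normalized. Signals were then raised to a floor at the pooled 5th percentile (a signal of 10.13) and put on the log2 scale. No probe set was removed from the gene comparisons. Background was the 95th percentile of the phage and plasmid probe sets, a normalized signal of 350. Arrays give no counts, so signal over background and the 5 arrays per pH limit the precision.

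With limma 3.58.1 in R 4.3.3, 1 mean per pH was fitted to all 15 arrays, with empirical Bayes variances that follow a trend with signal. A moderated F-test compared the 3 pH values and moderated contrasts compared each pair. Each test was adjusted by Benjamini-Hochberg over the 4345 gene probe sets and called at an adjusted p under 0.05. Intergenic probe sets were fitted on their own. A list of 28 gene groups was tested by camera with a preset correlation of 0.01, adjusted over the 28 lists of a comparison, and again with an estimated correlation and with fry. The lists were flagella and chemotaxis, amino acid-dependent acid resistance, acid fitness island and periplasmic acid chaperones, ATP synthase, NADH dehydrogenase I, cytochrome bo and bd oxidases, TCA cycle, hydrogenases, oxidative stress, monovalent cation transport, amino acid catabolism, maltose regulon, sugar and polyol use, heat shock and proteases, envelope stress, RpoS-dependent stress, ribosomal proteins, phage shock, outer membrane proteins, iron acquisition and storage, anaerobic respiration and fermentation, arginine biosynthesis, purine and pyrimidine biosynthesis, cysteine and sulfate assimilation, SOS response, phosphate regulon, colanic acid and capsule, and drug efflux. One probe set per gene, that of the highest mean, entered a list.

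Where all 5 arrays of a pH lay below background, the gene is called dim at that pH. The fold of a gene dim at 1 pH is a bound, the geometric mean at the brighter pH divided by background, and genes dim at both carry no fold. In the text the same bound stands for named genes whose mean at 1 pH, though not all 5 arrays, lay below background, a rule added after the data were seen. Medians of lists are of fitted log2 fold changes. The median with members at their bound, leaving out those dim at both pH values, is added where it differs by more than 0.1. Named genes were, in each pair, the 10 highest and 10 lowest log2 fold changes among called genes with non-overlapping arrays, up to 4 members of each called list in its direction and 2 in the other, up to 5 per class of genes called in both comparisons with pH 7.0, and a fixed set of pH, respiration, motility and stress genes. A selection of these is printed. The lists, tests, thresholds, this rule and the alternatives tried, other than those added later, were fixed before the data were examined. The background, the dim label and the bounds are not recorded as fixed then.

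Overlap between the comparisons that share the pH 7.0 arrays was set beside 20 simulations of unchanged groups and beside splits in which each comparison used its own pH 7.0 arrays. Alternatives tried were the deposited scaling, median centring and a rank-invariant scaling to pH 7.0 replicate 1, no floor or a floor at the 25th percentile, filters on dim probe sets, no variance trend, array weights, a stricter threshold of 0.001, the test described in the series text, fits of 2 pH values alone, each array left out in turn, and replicate number, chip lot, fluidics protocol or scan day as a block. Fits within 1 chip lot or 1 protocol, a filter at background, and leaving out the 2 arrays that stood apart were added after the data were seen. The steps were tested on simulated data with known changes on 4345 genes. In the comparison of pH 5.0 with pH 7.0, 32.8%, 73.1% and 95.5% of genes changed by 1.5-, 2- and 4-fold were recovered, with 7.59% false calls. For pH 8.7 against pH 7.0 the shares were 34.3%, 64.2% and 90.9%, with 4.55% false. Camera called 4 of 4 shifted sets and 0 of 24 unshifted ones. The simulated genes varied independently, without batches, and the sets were random. In the real lists the estimated correlation between members reached 0.529, so these rates may not hold for them. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.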

Results

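Transcript levels of E. coli K-12 W3110 in growth at a constant external pH were measured on 15 arrays, from 5 independent cultures each at pH 5.0, 7.0 or 8.7. The median signal of a deposited array ran from 198 to 318, and 56.3% to 59.6% of the gene probe sets of an array lay above background. Pearson's r across probe sets was 0.930 to 0.983 for 30 pairs of arrays of the same pH and 0.911 to 0.943 for 75 pairs of different pH. The mean lay above background at 1 pH or more for 2775 of the 4345 gene probe sets. Among the 3 pH values, 1673 gene probe sets (38.5%) differed by limma's F-test. All pH 7.0 arrays and pH 8.7 replicates 2, 3 and 4 were run with an earlier fluidics protocol, and all pH 5.0 arrays and pH 8.7 replicates 1 and 5 with a later one. All pH 7.0 arrays were scanned on 1 of 8 days, and no day held arrays of more than 1 pH.

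**Figure D1:**
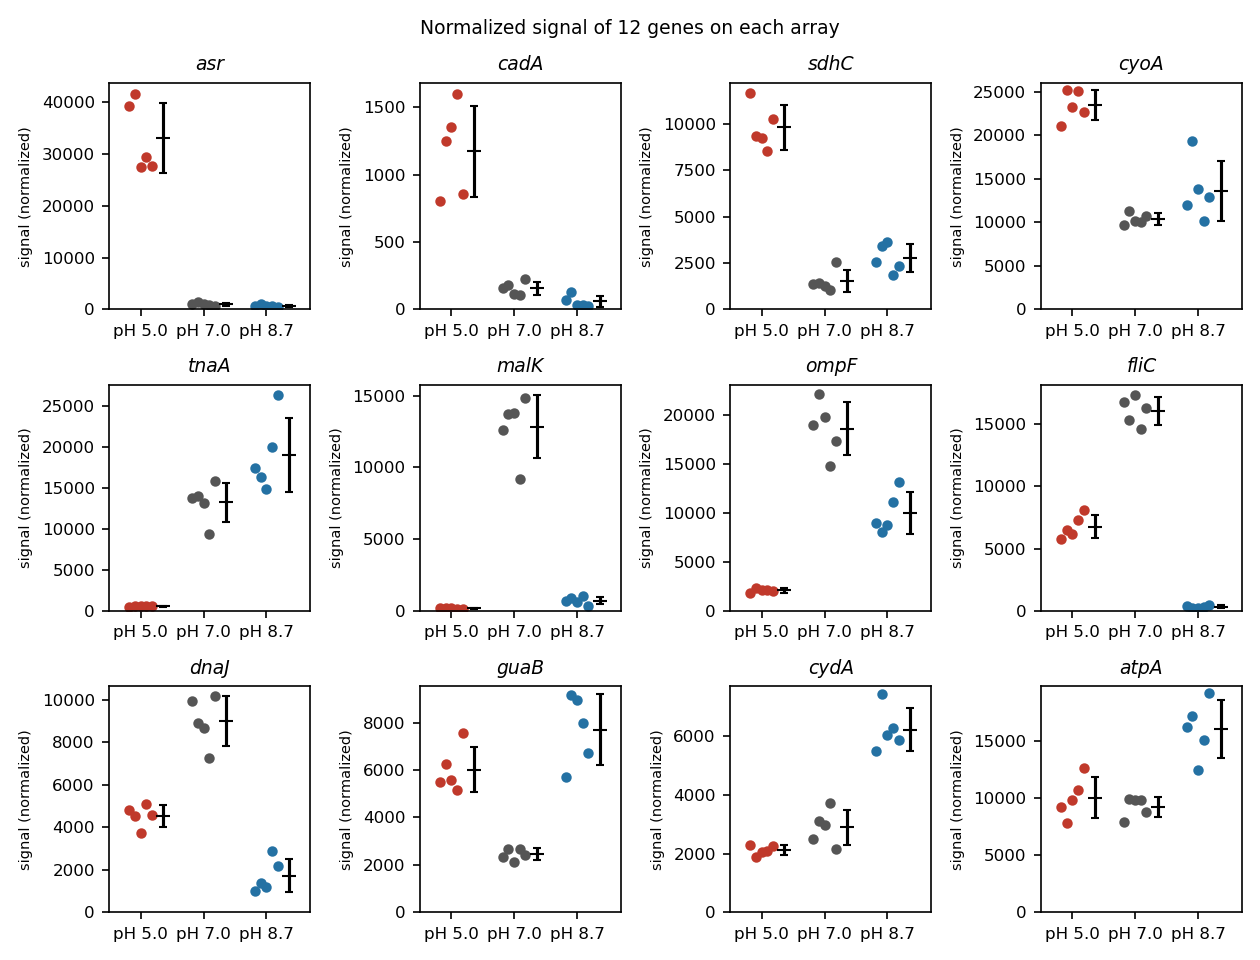
Normalized signal (linear axis from 0) of 12 genes at each of the 3 pH values, with each point 1 array (n = 5 per pH) and the bar beside them the mean ± SD. The asr signal was 33050 ± 6790 at pH 5.0, 982.9 ± 268 at pH 7.0 and 722.5 ± 218 at pH 8.7, malK reached 12840 ± 2200 at pH 7.0, and fliC fell from 16050 ± 1100 at pH 7.0 to 335.8 ± 108 at pH 8.7.

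The comparison of pH 5.0 with pH 7.0 asked which transcripts differ between acidic and neutral growth. At pH 5.0, asr, which encodes an acid-induced periplasmic protein, reached a signal of 33050 ± 6790 against 982.9 ± 268 (SD, n = 5 each), a log2 fold change of 5.09 (SE 0.22). The lysine decarboxylase gene cadA, whose enzyme consumes protons, was at 1172 ± 338 and at least 3.23-fold higher. Its transporter gene cadB was at least 1.13-fold higher. Maltose transport genes showed the opposite, with malK, the ATPase subunit, at least 36.2-fold lower than its pH 7.0 signal of 12840 ± 2200. Tryptophanase, tnaA, fell from 13240 ± 2370 to 565.6 ± 80.9 (log2 fold change −4.54, SE 0.17). The porin gene ompF fell from 18570 ± 2740 to 2085 ± 211 (−3.15, SE 0.14). In all, 1248 of 4345 gene probe sets (28.7%) were called by limma, 621 higher and 627 lower at pH 5.0, and 498 of them changed at least 2-fold. The arrays of both pH values did not overlap for 935 of the 4345 (21.5%), against 0.794% by chance, and 840 of these were called. They did overlap for tsuA, sodA, cydA, htpG, cadC and adiY among the called genes named for this comparison.

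Genes of the TCA cycle rose together, with 14 of 17 higher and 0 lower (15 adjusted over the list alone) and a median log2 fold change of 0.68. Camera gave an adjusted p of 8.39e-09, and adjusted p = 0.102 with an estimated correlation. Succinate dehydrogenase, which links the cycle to the respiratory chain, had sdhC at 9811 ± 1200 against 1528 ± 590 (2.75, SE 0.22) and sdhA at 16450 ± 1850 against 4822 ± 1440 (1.82, SE 0.18). The fumarase gene fumC was at least 2.19-fold higher. Outside the list, mqo, the malate:quinone oxidoreductase, was at 4763 ± 377 against 512.8 ± 224 (3.34, SE 0.45). A glucose dehydrogenase gene of the membrane, gcd, was at 1930 ± 362 against 169.8 ± 134, a mean below background, and at least 5.42-fold higher. NADH dehydrogenase I, the proton-pumping entry of the respiratory chain, had 6 of 13 higher and 0 lower (7 alone, median 0.36, camera adjusted p = 0.00221, adjusted p = 0.314 with an estimated correlation). Among them nuoI was at 0.82 (SE 0.12) and nuoA at 0.68 (SE 0.19). Of 11 cytochrome oxidase genes, 5 rose and 1 fell, the same numbers when adjusted over the list alone (median 0.29, or 0.56 at bounds, camera adjusted p = 0.00563, adjusted p = 0.252 with an estimated correlation). Those that rose were the 5 cytochrome bo genes, among them cyoA, at 23480 ± 1760 against 10390 ± 669 (1.18, SE 0.14), and cyoE (1.36, SE 0.17). The 1 that fell was cydA of cytochrome bd (−0.43, SE 0.13, adjusted p = 0.020, which was 0.0502 without pH 5.0 replicate 2 and 0.0518 without pH 7.0 replicate 4). That call was also lost with the deposited scaling (−0.394, adjusted p = 0.0514) and median centring (−0.344, 0.221).

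Acid resistance lists were called higher, with most members near background. Of 14 genes of amino acid-dependent acid resistance, 5 were called higher and 0 lower (5 alone). These were cadA, cadB and the regulator genes cadC, adiY and gadX, of which the regulator genes lay below background on all arrays of both pH values. In all, 11 of the 14 were dim at both, gadA, gadB and adiA included. Single arrays ended the calls of gadX (adjusted p = 0.0505 without pH 5.0 replicate 4) and cadC (0.059 to 0.0845 without pH 5.0 replicates 1 or 3 or pH 7.0 replicates 1, 3 or 5). The list median was 0.64, or 0.18 at bounds (camera adjusted p = 0.0175, adjusted p = 0.102 with an estimated correlation). Among 13 genes of the acid fitness island and periplasmic chaperones, 4 rose and 0 fell (4 alone, median 0.70, or 1.05 at bounds, camera adjusted p = 0.00842, adjusted p = 0.102 with an estimated correlation), and 10 were dim at both. Besides asr and gadX, the latter below background at both pH values, these were hdeA, a periplasmic chaperone, at 810.5 ± 228 against 389.8 ± 102 (1.05, SE 0.24), and hdeB, at least 1.04-fold higher. The oxidative stress list had 12 of 29 higher and 3 lower (13 and 3 alone, median 0.39, camera adjusted p = 0.00454, adjusted p = 0.102 with an estimated correlation). Glutaredoxin grxA was at 3930 ± 1040 against 791 ± 143 (2.30, SE 0.18). The DNA-protecting dps was at 3184 ± 736 against 888.7 ± 184 (1.84, SE 0.22), and the peroxidase subunit ahpF at 6210 ± 759 against 2638 ± 568 (1.25, SE 0.20). The superoxide dismutase gene sodB was higher (0.70, SE 0.16), the iron-sulfur assembly gene sufB lower (−0.80, SE 0.18). Catalase katG was at −0.40 (adjusted p = 0.10), but was called lower with the fluidics protocol (−1.08, adjusted p = 0.0073) or the chip lot (−0.545, 0.0243) as a block. The calls of sodA (0.41, adjusted p = 0.044) and sufC (−0.79, adjusted p = 0.037) were each lost when any 1 of 8 of the 10 arrays of these pH values was left out (adjusted p up to 0.0961 and 0.0953). RpoS-dependent stress genes had 9 of 23 higher and 0 lower (9 alone, median 0.56, or 0.34 at bounds, camera adjusted p = 0.00139, adjusted p = 0.149 with an estimated correlation). They included cfa, which makes cyclopropane fatty acids (at least 5.56-fold higher than a pH 7.0 mean below background). The sigma factor gene rpoS itself was at −0.40 (adjusted p = 0.15), and without pH 7.0 replicate 2 it was lower (−0.58, adjusted p = 0.0202).

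The maltose regulon fell, with 9 of 12 lower and 0 higher (10 alone) and a median of −3.44, or −3.77 at bounds. Its camera adjusted p was 2.93e-14 and it is the only list of this comparison called both ways, with adjusted p = 0.0164 with an estimated correlation. The maltoporin lamB was at 390.3 ± 42.2 against 16150 ± 2490 (−5.36, SE 0.16), the maltose-binding protein malE at 632.8 ± 42 against 16040 ± 2790 (−4.65, SE 0.17). The phosphorylase gene malP was at −4.70 (SE 0.14). Sugar and polyol genes had 12 of 67 higher and 25 lower (13 and 28 alone, median −0.35, or −0.05 at bounds, camera adjusted p = 0.0171, adjusted p = 0.461 with an estimated correlation, and adjusted p = 0.0667 without pH 7.0 replicate 5). The trehalose genes treB (−3.75, SE 0.16) and treC (−3.32, SE 0.13) were lower, and the glucose transporter ptsG was higher (1.14, SE 0.13). Amino acid catabolism had 13 of 25 lower and 2 higher (13 and 4 alone, median −0.70, or −0.26 at bounds, camera adjusted p = 3.62e-04, adjusted p = 0.149 with an estimated correlation). Among them tnaC, the leader of the tryptophanase operon, was at 642.2 ± 352 against 26930 ± 5290 (−5.50, SE 0.25). Serine deaminase sdaB was at −1.95 (SE 0.23) and D-amino acid dehydrogenase dadA at 1.67 (SE 0.22).

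Iron genes had 22 of 37 lower and 0 higher (25 alone, median −0.78, or −0.67 at bounds, camera adjusted p = 7.98e-12, adjusted p = 0.149 with an estimated correlation). The ferric citrate receptor fecA was at 364.2 ± 148 against 4482 ± 529 (−3.70, SE 0.22) and fecB, its binding protein, at least 6.77-fold lower. Heat shock genes had 13 of 17 lower and 0 higher (14 alone, median −0.98, camera adjusted p = 2.53e-05, adjusted p = 0.301 with an estimated correlation). They included the protease htpX (−1.59, SE 0.21), the small chaperone ibpB (−2.43, SE 0.44) and htpG (−1.44, SE 0.44). The call of htpG was lost without pH 5.0 replicate 1 (adjusted p = 0.0528), pH 5.0 replicate 2 (0.0534) or pH 7.0 replicate 1 (0.0519). Phosphate genes had 7 of 17 lower and 0 higher (9 alone, median −0.57, or −0.81 at bounds, camera adjusted p = 6.95e-04, adjusted p = 0.102 with an estimated correlation). Among them the binding protein pstS was at 911.4 ± 251 against 7131 ± 1130 (−2.99, SE 0.44). Flagella and chemotaxis had 23 of 54 lower and 2 higher (25 and 2 alone, median −0.25, camera adjusted p = 4.19e-04, adjusted p = 0.314 with an estimated correlation). The response regulator cheY was at 1289 ± 147 against 5677 ± 874 (−2.13, SE 0.15), flagellin fliC at 6775 ± 943 against 16050 ± 1100 (−1.25, SE 0.18) and fliR, of the export apparatus, at 1.18 (SE 0.23). The regulators flhD (−0.13) and fliA (−0.20) were not called. Cysteine and sulfate genes had 11 of 24 higher and 1 lower, in both adjustments (median 0.29, or 0.19 at bounds, camera adjusted p = 0.0359, adjusted p = 0.314 with an estimated correlation). Among them cysD, of sulfate activation, was at least 1.3-fold higher. That list call was lost without pH 5.0 replicate 1 (adjusted p = 0.0526), pH 5.0 replicate 2 (0.0572) or pH 7.0 replicate 2 (0.153).

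Further genes at the ends of the ranking were the inner membrane gene yagU, at least 8.99-fold higher, and lysA of lysine synthesis, at least 2.4-fold higher. At the other end were the pyruvate transporter btsT, at least 29.3-fold lower than 10300 ± 1110, and the prophage porin nmpC, at 608.8 ± 134 against 17210 ± 2870 (−4.83, SE 0.16). The proline tRNA gene proL was at least 1.15-fold higher, on probes shared between genes. The other 13 lists were not called, though 5 of them were with the protocol as a block. Envelope stress had 1 of 16 higher and 7 lower (median −0.23, adjusted p = 0.0696, or 0.0467 without pH 5.0 replicate 3) and outer membrane proteins 4 and 6 of 18 (−0.17, or −0.06 at bounds, adjusted p = 0.0615, or 0.044 to 0.0485 without pH 5.0 replicates 2, 3 or 4 or pH 7.0 replicate 3). Colanic acid had 2 higher and 4 lower of 22 (−0.23, or 0.00 at bounds, 0.663), hydrogenases 0 and 2 of 30 (−0.13, 0.386) and phage shock 0 and 1 of 7 (−0.32, 0.0722). Monovalent cation transport had 2 higher and 3 lower of 15 (−0.33, or −0.17 at bounds, 0.227), with the sodium antiporter nhaA at −0.51 (SE 0.15). Purine and pyrimidine synthesis had 7 and 1 of 22 (0.10, 0.0867), anaerobic respiration and fermentation 10 and 1 of 27 (0.08, 0.227), and drug efflux 6 and 3 of 21 (0.17, or 0.03 at bounds, 0.227). The SOS response had 1 and 0 of 20 (0.17, 0.322), arginine synthesis 2 and 2 of 12 (−0.03, 0.663), ribosomal proteins 4 and 4 of 54 (0.08, 0.300) and ATP synthase 0 and 0 of 9 (0.06, 0.747).

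This comparison cannot be made within 1 fluidics protocol, since each protocol held only 1 of the 2 pH values. With the protocol as a block, which the pH 8.7 arrays allow, 514 gene probe sets were called, 305 higher and 209 lower, against 621 and 627 without it. Of the 1248, 372 stayed called and 1170 kept their sign, and standard errors grew by a median factor of 1.72. List medians in that fit were −3.56 for maltose, 0.72 for the TCA cycle, −1.21 for heat shock, −0.53 for iron, −0.50 for amino acid catabolism and 0.46 for cytochrome oxidases. They were 0.79 for NADH dehydrogenase I, 0.75 for RpoS-dependent stress, 1.23 for the acid fitness island, 1.09 for cysteine, −0.64 for phosphate, 0.29 for oxidative stress and −0.12 for sugars, and 0.01 for flagella, whose test still pointed down, and all of these lists were still called. Fewer of their members were, with 6 of 17 higher for the TCA cycle, 7 of 17 lower for heat shock, 6 of 37 lower for iron and 12 of 54 lower for flagella. Only maltose (9 lower) and NADH dehydrogenase I (9 higher) had no fewer. Lists that gained a call with the block were envelope stress (−0.53, adjusted p = 0.00102), outer membrane proteins (−0.56, 3.3e-04), phage shock (−0.54, 0.0257), arginine synthesis (−0.44, 0.0419) and the SOS response (0.42, 0.0435). Amino acid-dependent acid resistance, at 0.46, lost its call (adjusted p = 0.106). Among named genes, the block moved mqo to 1.5 (adjusted p = 0.11), ahpF to 0.42 (0.34), cyoE to 0.58 (0.051), and hdeA to 1.23 (0.076), none of them still called. Also no longer called were sodB at 0.16 (0.74), nhaA at −0.16 (0.76), sufB at −0.27 (0.62), ibpB at −2.45 (0.059), and cydA at −0.22 (0.60). Among these, ibpB and hdeA kept their size and lost the call to larger standard errors (0.44 to 0.79 and 0.24 to 0.42), while the others shrank. Of genes with a bound or below background, tsuA (adjusted p = 0.11) and cadC (0.30) also kept the size of the fitted difference, with standard errors of 1.19 and 0.74 in place of 0.66 and 0.41. For cfa (0.067), proL (0.89), tdcB (0.24) and adiY (0.65) it shrank. It turned sodA to −0.06 (adjusted p = 0.91) and sufC to 0.23 (0.77). With the scan day as a random block 736 were called, and cadC (adjusted p = 0.119), gadX (0.0638), cydA (0.0858), htpG (0.0791), nhaA (0.0623), sodA (0.122) and sufC (0.105) were among those no longer called. Their differences stayed (slope 0.999 over the 1248, with htpG at −1.42 and nhaA at −0.51), and the calls ended because standard errors grew by a median factor of 1.24. Each day held arrays of a single pH, so that block only reweights the arrays of a pH. The unchanged differences follow from the design and do not test a day effect. With the chip lot as a block, envelope stress (adjusted p = 0.0358), outer membrane proteins (0.0316), phage shock (0.0481), purine and pyrimidine synthesis (0.0481) and ribosomal proteins (0.0358) were called as well, and all but the purines were within chip lot 1 alone (0.0194 to 0.0399). Within chip lots 1 and 2, with 2 and 3 pH 5.0 arrays and 4 and 1 pH 7.0 arrays, 528 and 238 were called. The medians were −3.51 and −3.43 for maltose, 0.73 and 0.56 for the TCA cycle, −0.91 and −0.60 for iron and −1.06 and −1.14 for heat shock. The lone pH 7.0 array of lot 2 was taken to vary like the others. In that lot the calls of flagella (−0.16, adjusted p = 0.145), NADH dehydrogenase I (0.27, 0.101), RpoS-dependent stress (0.46, 0.145), the acid fitness island (0.35, 0.103), amino acid-dependent acid resistance (0.44, 0.0515), oxidative stress (0.34, 0.0785), phosphate (−0.64, 0.0515) and cysteine (0.07, 0.881) were lost. Without pH 5.0 replicate 1 and pH 7.0 replicate 2, the arrays that stood apart, 1214 were called and only the cysteine list lost its call (median 0.00, adjusted p = 0.205), while rpoS was called lower (−0.639, 0.0177). The calls of htpG (0.0788), gadX (0.0839), sodA (0.067) and sufC (0.102) were lost there, among others.

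The comparison of pH 8.7 with pH 7.0 asked which transcripts differ between alkaline and neutral growth. Flagellar genes fell nearly throughout, with 51 of 54 lower and 0 higher (53 lower alone) and a median log2 fold change of −1.38. Flagellin, fliC, went from a signal of 16050 ± 1100 to 335.8 ± 108 (SD, n = 5 each), a mean below background and at least 45.8-fold lower, and the motor gene motB was at least 8.11-fold lower. The sigma factor of late flagellar genes, fliA, went from 10350 ± 513 to 4948 ± 1230 (−1.10, SE 0.14). Purine and pyrimidine synthesis rose, with 18 of 22 higher and 0 lower (19 alone). Among them guaB of guanine nucleotide synthesis was at 7707 ± 1480 against 2452 ± 243 (1.64, SE 0.14). ATP synthase rose as well, with 8 of 9 higher and 0 lower (9 alone), atpA at 16070 ± 2520 against 9270 ± 876 (0.78, SE 0.13) and atpB at 0.79 (SE 0.11). In all, limma called 898 of 4345 gene probe sets (20.7%), 450 higher and 448 lower at pH 8.7, 384 of them by at least 2-fold. The arrays did not overlap for 610 of the 4345 (14%), against 0.794% by chance, and 580 of these were called. They did overlap for htpX and tnaA among the called genes named for this comparison.

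Camera gave the flagella an adjusted p of 8.84e-57, with adjusted p = 0.00107 with an estimated correlation. For purine and pyrimidine synthesis (median 1.06, or 0.80 at bounds) these were 1.02e-14 and adjusted p = 0.00195 with an estimated correlation, and for ATP synthase (median 0.77) 5.91e-07 and adjusted p = 0.00788 with an estimated correlation. The maltose regulon was the remaining list called both ways, with 9 of 12 lower and 1 higher in both adjustments and a median of −3.0 (camera adjusted p = 2.63e-11, adjusted p = 0.0118 with an estimated correlation). Within it, malK went from 12840 ± 2200 to 710.8 ± 252 (−4.24, SE 0.23), malP was at −4.12 (SE 0.14), lamB at −3.53 (SE 0.16) and malE at −3.70 (SE 0.17). The activator of the regulon, malT, was the 1 higher, at 834.8 ± 90.5 and at least 2.37-fold above a pH 7.0 mean below background. Chemotaxis genes were among the lowest of all, with cheW at 337.6 ± 110, below background, against 5135 ± 664 (at least 14.6-fold lower), cheZ at least 7.23-fold lower and pdeH, a cyclic di-GMP phosphodiesterase, at least 12.1-fold lower. The master regulator flhD was at −0.26 (adjusted p = 0.35) and was not called. The list's direction was the same at bounds, at −1.38.

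Heat shock genes fell, with 14 of 17 lower and 1 higher in both adjustments (median −2.18, camera adjusted p = 1.56e-09, adjusted p = 0.181 with an estimated correlation). The chaperone genes dnaJ went from 8988 ± 1170 to 1731 ± 783 (−2.48, SE 0.23) and clpB from 3149 ± 762 to 550.1 ± 267 (−2.62, SE 0.30). Also lower, htpG went from 3938 ± 930 to 580.9 ± 353 (−3.03, SE 0.44), and ibpB was at least 8.32-fold lower. The 1 higher was htpX (0.63, SE 0.21, adjusted p = 0.046), which no longer passed in 11 of the fits without 1 array (highest adjusted p 0.116). Phosphate genes had 8 of 17 lower and 0 higher (10 alone, median −0.74, or −0.93 at bounds, camera adjusted p = 1.33e-04, adjusted p = 0.0575 with an estimated correlation). Among them phoB, their activator, was at least 4.35-fold lower and pstS at 1204 ± 1170 against 7131 ± 1130 (−3.04, SE 0.44). Iron genes had 8 of 37 lower and 0 higher (9 alone, median −0.36, camera adjusted p = 6.23e-04, adjusted p = 0.593 with an estimated correlation). Among them fecB was at −1.64 (SE 0.34). Cysteine and sulfate genes had 11 of 24 higher and 0 lower (12 alone, median 0.83, camera adjusted p = 1.31e-04, adjusted p = 0.181 with an estimated correlation). They included the sulfate transport gene cysU, at least 2.52-fold higher, and cysD, at least 2.05-fold higher.

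Smaller shifts were called in 5 more lists. Cytochrome oxidases had 4 of 11 higher and 0 lower (5 alone, median 0.21, camera adjusted p = 0.00515, adjusted p = 0.256 with an estimated correlation). Among them cydA of cytochrome bd was at 6221 ± 736 against 2895 ± 592 (1.12, SE 0.13), and cydB at 0.97 (SE 0.15). The cytochrome bo gene cyoA was at 0.36 (adjusted p = 0.073, or 0.45 and 0.0201 without pH 8.7 replicate 4). The SOS response, to DNA damage, had 4 of 20 higher and 0 lower in both adjustments (median 0.21, camera adjusted p = 0.00946, adjusted p = 0.227 with an estimated correlation). Among them dinI was at 1.21 (SE 0.15) and the division inhibitor sulA at 0.95 (SE 0.17). RpoS-dependent stress had 4 of 23 higher and 1 lower in both (median 0.36, or 0.21 at bounds, camera adjusted p = 0.0199, adjusted p = 0.352 with an estimated correlation, and 0.0765 without pH 7.0 replicate 2). The osmotically induced osmB was at 1.39 (SE 0.16), and rpoS at 0.38 (adjusted p = 0.21). Ribosomal proteins had 4 of 54 higher and 0 lower (3 alone, median 0.13, camera adjusted p = 0.00779, adjusted p = 0.673 with an estimated correlation, fry adjusted p = 0.0779). Among them rpsA was at 0.14 and not called. Colanic acid genes had 5 of 22 higher and 0 lower in both (median 0.25, or −0.06 at bounds with 10 members dim at both pH values, camera adjusted p = 0.0459, adjusted p = 0.409 with an estimated correlation). That call was lost, with adjusted p between 0.05 and 0.092, without any 1 of pH 5.0 replicates 1, 2 and 5, pH 7.0 replicates 2 and 5 and pH 8.7 replicates 2, 3 and 4.

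Among other genes at the ends of the ranking, bsmA, a biofilm and stress gene, was at least 6.21-fold higher, and hisD of histidine synthesis at least 1.92-fold higher. The transcript of ymgD was at 2633 ± 652 against 402.3 ± 62.5 (2.69, SE 0.16). The envelope stress chaperone spy was at 2505 ± 384 against 764.4 ± 85.2 (1.71, SE 0.14). The antiporter gene nhaA, whose protein exchanges sodium for protons, was at 1131 ± 208 against 758.6 ± 64.1 (0.56, SE 0.15). The porin gene ompF was lower (−0.91, SE 0.14) and ompC higher (0.36, SE 0.10, adjusted p = 0.018, or 0.0526 without pH 7.0 replicate 3 and 0.0713 to 0.218 with the other 3 scalings). Tryptophanase tnaA was higher by 0.51 (SE 0.17, adjusted p = 0.038), which single arrays at pH 7.0 (replicates 1, 3 and 4) or pH 8.7 (replicates 1, 4 and 5) raised to 0.052 to 0.0985 when left out. The transcripts of asr (−0.45, adjusted p = 0.16), sdhA (0.07), sodA (−0.13) and katG (−0.29) were not called, though katG was lower with the protocol as a block (−0.56, adjusted p = 0.020). The transcripts of gadA, gadB, adiA, cadB, hyaA and hycA were dim at both pH values. Lists not called were NADH dehydrogenase I, with 1 of 13 higher and 1 lower (median 0.23, adjusted p = 0.168, or 0.0453 without pH 8.7 replicate 1), and the TCA cycle with 2 and 6 of 17 (−0.15, 0.165, or 0.0232 without pH 7.0 replicate 4 and 0.0337 without pH 8.7 replicate 5). Sugar and polyol use had 11 and 18 of 67 (0.00, mean −0.25, 0.222, or 0.0402 without pH 7.0 replicate 4). Amino acid catabolism had 5 and 4 of 25 (0.01, 0.558), amino acid-dependent acid resistance 1 and 2 of 14 (−0.20, 0.621), and the acid fitness island 2 and 3 of 13 (−0.29, 0.808). For hydrogenases the numbers were 0 and 1 of 30 (−0.25, or −0.12 at bounds, 0.272) and for envelope stress 4 and 2 of 16 (0.18, 0.355). Oxidative stress had 3 and 1 of 29 (−0.04, with the test pointing up, 0.904), monovalent cation transport 3 and 2 of 15 (−0.22, or −0.04 at bounds, with the test pointing up, 0.904) and outer membrane proteins 2 and 4 of 18 (0.15, mean −0.21, 0.808). Phage shock had 0 and 0 of 7 (0.02, 0.819), anaerobic respiration and fermentation 1 and 2 of 27 (−0.07, 0.808), arginine synthesis 3 and 0 of 12 (0.13, or 0.00 at bounds, 0.168) and drug efflux 2 and 3 of 21 (0.07, 0.808).

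With the fluidics protocol as a block 806 gene probe sets were called, and within the earlier protocol 595. Only pH 8.7 held both protocols, so both fits take this difference from the same arrays. They give the same estimate with different standard errors and are not separate support. The medians within the earlier protocol were −1.33 for flagella, 0.96 for purine and pyrimidine synthesis, 0.57 for ATP synthase, −3.05 for maltose, −2.10 for heat shock, −0.75 for phosphate and −0.23 for iron. They were 0.94 for cysteine, 0.20 for cytochrome oxidases, 0.35 for SOS, 0.30 for RpoS-dependent stress, 0.12 for ribosomal proteins and 0.32 for colanic acid, and each of these lists was called. Lists that gained a call within the earlier protocol and with the block were NADH dehydrogenase I (0.39, adjusted p = 0.0063 and 0.00414) and the TCA cycle (−0.17, 0.0126 and 0.00878), with 6 of 13 higher and 7 of 17 lower in the block. Chip lot 1 alone also called the former (adjusted p = 2.66e-04), and chip lot 2 the latter (9.29e-04) and the sugars and polyols (9.2e-04). As a block, the protocol ended the calls of RpoS-dependent stress (median 0.30, adjusted p = 0.061), tnaA (0.18), ompC (0.099) and htpX (0.19). All 898 called gene probe sets kept their sign with that block (slope 0.989), and standard errors grew by a median factor of 1.13. With the scan day as a random block 514 were called, 266 higher and 248 lower. That block ended the calls of tnaA (adjusted p = 0.149), ompC (0.071), htpX (0.161), nhaA (0.054) and tsuA (0.0609), among others. The differences stayed (tnaA at 0.50, ompC at 0.36, htpX at 0.63 and nhaA at 0.56), and standard errors grew by a median factor of 1.26. As each day held a single pH, the differences could hardly move with that block, and this does not test a day effect. With the chip lot as a block RpoS-dependent stress (0.0817), htpX (0.20) and tnaA (0.207) lost theirs, among others. In that fit all 898 called gene probe sets kept their sign (slope 1.002), and standard errors grew by a median factor of 1.15. Within chip lots 1 and 2, with 4 and 1 pH 7.0 arrays and 1 and 4 pH 8.7 arrays, 250 and 220 were called, the lone array of a pH being taken to vary like the others. The medians there were −1.47 and −1.19 for flagella, 1.25 and 1.06 for purines, 0.78 and 0.83 for ATP synthase, −3.06 and −3.04 for maltose, and −2.39 and −2.17 for heat shock. Calls lost in a lot were RpoS-dependent stress in lot 1 (0.42, adjusted p = 0.063) and lot 2 (−0.01, 0.639), colanic acid in lot 1 (0.53, 0.0555) and iron in lot 2 (−0.08, 0.24). Without the 2 arrays that stood apart 901 were called, and RpoS-dependent stress (0.19, adjusted p = 0.076) and colanic acid (0.05, 0.0792) lost their calls.

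**Figure D2:**
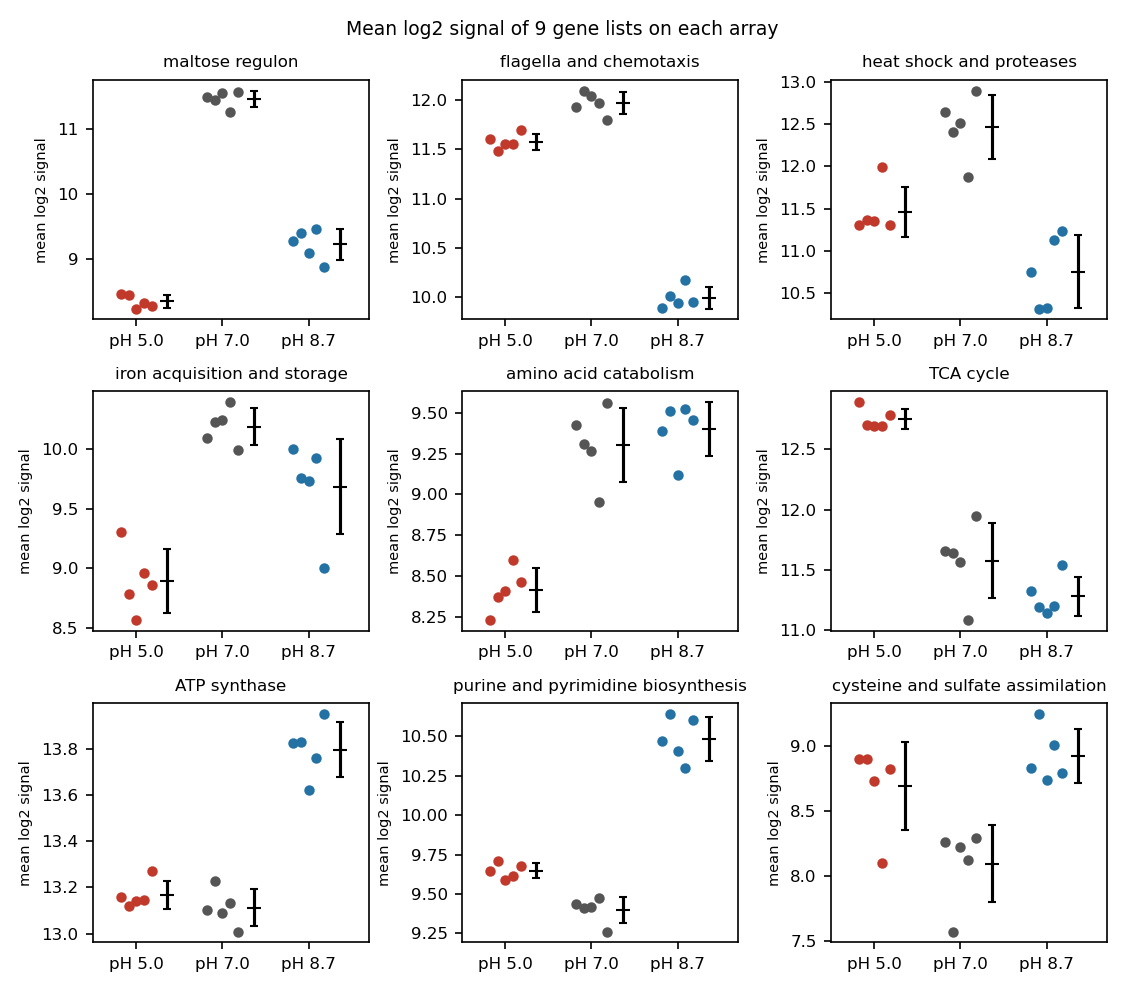
Mean log2 normalized signal of 9 gene lists on each array of the 3 pH values, with each point 1 array (n = 5 per pH) and the bar beside them the mean ± SD. The flagellar points lie lowest at pH 8.7 (median log2 fold change against pH 7.0 −1.38), those of the TCA cycle highest at pH 5.0 (0.68) and those of maltose highest at pH 7.0 (−3.44 at pH 5.0 and −3.0 at pH 8.7).

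The comparison of pH 8.7 with pH 5.0 spanned the whole range tested. Tryptophanase tnaA was at 18980 ± 4500 at pH 8.7 and 565.6 ± 80.9 at pH 5.0 (SD, n = 5 each, log2 fold change 5.05, SE 0.17), and its leader tnaC at 40950 ± 7530 and 642.2 ± 352 (6.11, SE 0.25). Trehalose uptake and cleavage genes treB (4.73, SE 0.16) and treC (4.23, SE 0.13) were also higher at pH 8.7, as was nmpC (4.96, SE 0.16). The acid-induced asr was lower by −5.54 (SE 0.22), cadA at least 3.23-fold lower and yagU at least 8.99-fold lower. Succinate dehydrogenase sdhA was at 4929 ± 723 against 16450 ± 1850 (−1.74, SE 0.18). Flagellin fliC was at 335.8 ± 108, below background, against 6775 ± 943 (at least 19.2-fold lower). In all, limma called 1132 of 4345 gene probe sets (26.1%), 533 higher and 599 lower at pH 8.7, 525 by at least 2-fold. The arrays did not overlap for 826 of the 4345 (19%), against 0.794% by chance, and 782 of these were called. They did overlap for atpA, sodA and sodB among the called genes named for this comparison. The call of sodB (−0.48, SE 0.16) was lost without any 1 of pH 5.0 replicates 1 and 2 and pH 8.7 replicates 2, 3 and 4 (adjusted p = 0.0566 to 0.092). It was also lost with the deposited scaling (0.0578), median centring (0.16), no variance trend (0.0507) and the fit of these pH values alone (0.0548).

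Flagella had 52 of 54 lower and 0 higher in both adjustments (median −1.40, camera adjusted p = 2.78e-40, adjusted p = 0.00533 with an estimated correlation). Among them fliA was at −0.90 (SE 0.14) and motB at least 2.82-fold lower. ATP synthase had 8 of 9 higher and 0 lower (9 alone, median 0.67, camera adjusted p = 2.09e-05, adjusted p = 0.0233 with an estimated correlation). Among them atpB was at 0.85 (SE 0.11) and atpA at 0.68 (SE 0.13). Purine and pyrimidine synthesis had 15 of 22 higher and 0 lower (17 alone, median 0.72, camera adjusted p = 2.85e-08, adjusted p = 0.0233 with an estimated correlation). Among them purM was at 1806 ± 274 against 464.5 ± 88.5 (1.97, SE 0.15). These 3 lists were called with both correlations. The TCA cycle had 14 of 17 lower and 0 higher in both adjustments (median −1.67, camera adjusted p = 6.16e-11, adjusted p = 0.0741 with an estimated correlation). Among them sucA of 2-oxoglutarate dehydrogenase was at 3797 ± 905 against 14700 ± 2230 (−1.97, SE 0.17). Outside that list, mqo was at 319.1 ± 226, below background, against 4763 ± 377 (at least 13.6-fold lower), and gcd at least 5.42-fold lower.

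Iron genes had 17 of 37 higher and 0 lower (20 and 1 alone, median 0.51, camera adjusted p = 2.94e-06, adjusted p = 0.32 with an estimated correlation). Among them the siderophore receptor cirA was at 2834 ± 880 against 384 ± 152 (2.93, SE 0.28) and fecA at 2.27 (SE 0.22). Maltose genes had 8 of 12 higher and 0 lower in both adjustments (median 0.70, camera adjusted p = 2.09e-05, adjusted p = 0.0863 with an estimated correlation). Among them lamB was at 1.83 (SE 0.16) and malK at least 1.91-fold higher. Amino acid catabolism had 13 of 25 higher and 2 lower (13 and 3 alone, median 0.62, or 0.07 at bounds, camera adjusted p = 2.77e-04, adjusted p = 0.134 with an estimated correlation). Among them dadA was at −1.80 (SE 0.22). Heat shock had 9 of 17 lower and 1 higher (10 and 1 alone, median −0.98, or −0.84 at bounds, camera adjusted p = 0.00879, adjusted p = 0.455 with an estimated correlation). Among them clpB was at −2.31 (SE 0.30), dnaJ at −1.50 (SE 0.23) and htpX the 1 higher (2.22, SE 0.21). Oxidative stress had 10 of 29 lower and 0 higher in both (median −0.21, camera adjusted p = 0.0138, adjusted p = 0.0824 with an estimated correlation). Among them grxA was at 730.4 ± 161 against 3930 ± 1040 (−2.42, SE 0.18), dps at −1.63 (SE 0.22) and ahpF at −1.64 (SE 0.20). Amino acid-dependent acid resistance was lower, with 4 of 14 lower and 0 higher in both (median −0.67, or −0.18 at bounds with 10 dim at both pH values, camera adjusted p = 0.0164, adjusted p = 0.0741 with an estimated correlation). So was the acid fitness island, with 4 of 13 lower and 0 higher in both (median −0.70, camera adjusted p = 0.0275, adjusted p = 0.134 with an estimated correlation). Among their members hdeA was at 323.4, below background, against 810.5 ± 228 (at least 2.25-fold lower) and hdeB at least 1.04-fold lower. Colanic acid had 7 of 22 higher and 1 lower (8 and 1 alone, median 0.69, or 0.01 at bounds with 10 dim at both pH values, camera adjusted p = 0.0164, adjusted p = 0.266 with an estimated correlation). The 1 lower was rcsA, a capsule activator (at least 2.46-fold lower).

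Other genes at the ends of the ranking were btsT, at least 16.8-fold higher, ldtC, a cell wall transpeptidase, at least 13.8-fold higher, and yhcN, at least 12.6-fold lower. Cytochrome bd cydA was at 6221 ± 736 against 2117 ± 164 (1.55, SE 0.13) and cytochrome bo cyoA at 13640 ± 3470 against 23480 ± 1760 (−0.81, SE 0.14). Their list had 4 of 11 higher and 5 lower and was not called (median −0.08, or −0.45 at bounds, adjusted p = 0.652). The porin ompF (2.24, SE 0.14), nhaA (1.07, SE 0.15) and rpoS (0.78, SE 0.20) were higher and sodA was lower (−0.54, SE 0.14), a call lost with the deposited scaling (−0.402, adjusted p = 0.112) and median centring (−0.399, 0.254). The transcripts of katG (0.11), rpsA (0.10), flhD (−0.13) and ompC (−0.23) were not called, though with the protocol as a block flhD was lower (−0.557, adjusted p = 0.032) and within the later protocol katG was higher (0.523, 0.0369). Of the lists not called, NADH dehydrogenase I had 0 of 13 higher and 1 lower (−0.24, adjusted p = 0.0759, or 0.0151 and 0.030 without pH 8.7 replicates 2 and 3) and envelope stress 7 and 5 of 16 (0.28, 0.0759, or 0.0337 and 0.0435 without the same arrays). Arginine synthesis had 3 and 0 of 12 (0.29, 0.065, or 0.0337 to 0.0437 without pH 8.7 replicates 2, 3 or 4) and outer membrane proteins 5 and 1 of 18 (0.06, 0.105, or 0.0435 without pH 8.7 replicate 3). Phage shock had 1 and 0 of 7 (0.31, 0.109, or 0.0486 without pH 8.7 replicate 3) and ribosomal proteins 2 and 0 of 54 (0.08, 0.133, or 0.0433 without pH 5.0 replicate 1). The ribosomal list depended on the scaling. It was called by camera with the deposited scaling (median 0.435, adjusted p = 4.56e-06) and median centring (0.438, 3.98e-04). SOS had 5 and 1 of 20 (0.23, or 0.11 at bounds, 0.112), anaerobic respiration and fermentation 4 and 11 of 27 (−0.19, 0.174), cysteine 5 and 1 of 24 (0.01, 0.252) and sugars and polyols 18 and 15 of 67 (0.27, or 0.13 at bounds, 0.302). Monovalent cation transport had 4 and 3 of 15 (0.08, 0.335), RpoS-dependent stress 3 and 4 of 23 (−0.28, or 0.00 at bounds, 0.371), drug efflux 3 and 5 of 21 (0.11, mean −0.20, 0.58), hydrogenases 0 and 1 of 30 (0.877) and phosphate 1 and 0 of 17 (−0.05, 0.955).

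With the protocol as a block 879 gene probe sets were called, and within the later protocol 892. Here too both fits take the difference from the same arrays, so they give the same estimate and are not separate support. The medians within the later protocol were −1.47 for flagella, −1.32 for the TCA cycle, 0.76 for purines, 0.66 for ATP synthase, 0.67 for maltose and 0.38 for iron. They were 0.56 for amino acid catabolism, −0.30 for oxidative stress, −0.69 and −0.70 for the acid lists and 0.36 for colanic acid, and all these lists were called there. Heat shock (−0.70) lost its call within it (adjusted p = 0.13) and with the block (0.233). Lists that gained a call with the block and within the later protocol were NADH dehydrogenase I (−0.47, adjusted p = 2.84e-04 and 1.4e-04, 7 of 13 lower in the block), envelope stress (0.48, 0.00468 and 0.0193), outer membrane proteins (0.19, 0.00609 and 0.0185) and arginine synthesis (0.46, 0.00558 and 0.00613). So were phage shock (0.405, adjusted p = 0.0499 and 0.0331) and ribosomal proteins (0.06, 0.0499 and 0.029, and 0.0313 with the chip lot as a block). Chip lot 2 alone called NADH dehydrogenase I (adjusted p = 0.0172) and ribosomal proteins (0.0166) too. The block also ended the calls of colanic acid (0.36, adjusted p = 0.0621), sodA (−0.26, 0.29), sodB (−0.16, 0.61) and htpG (−0.70, 0.38). Within chip lots 1 and 2, with 2 and 3 pH 5.0 arrays and 1 and 4 pH 8.7 arrays, 360 and 834 were called. The medians were −1.5 and −1.30 for flagella and −1.65 and −1.54 for the TCA cycle. Amino acid-dependent acid resistance lost its call in lot 1 (−0.61, adjusted p = 0.138) and the acid fitness island in lot 2 (−0.41, 0.0662). With the scan day as a random block 994 were called, and no named gene lost its call. Without the 2 arrays that stood apart 1109 were called, ribosomal proteins gained a call (adjusted p = 0.0461), sodB lost its call (0.0756), and the acid fitness island lost its call (−0.57, adjusted p = 0.0585).

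Genes that differed from pH 7.0 at both other pH values included malK, lamB, malE, malP and malM of the maltose regulon, lower at both, by −5.36 and −3.53 for lamB. Sulfate activation genes cysN and cysD were higher at both, as were yeaQ and tsuA. In opposite directions, spy was at least 2.17-fold lower at pH 5.0 and higher by 1.71 at pH 8.7, and ldtC at least 4.57-fold lower and higher by 1.59, with yebE and tdcB in the same class. The tdcB signal was dim at pH 5.0 and pH 7.0, and its call at pH 5.0 was lost with the protocol as a block (adjusted p = 0.24). So was that of tsuA (0.11), whose fitted difference stayed (3.15 against 3.17) with a standard error of 1.19. The yhcN transcript was higher by 2.57 at pH 5.0 and at least 2.13-fold lower at pH 8.7. The genes yagU, cadA and fimD shared that class, cadA and fimD being dim at pH 7.0 and pH 8.7. Within the earlier protocol the pH 8.7 calls of cadA (0.0791), fimD (0.0983) and yeaQ (0.0792) were lost, and with the scan day as a random block that of tsuA (0.0609). Their fitted differences stayed near those of all arrays, so these losses came with fewer arrays or larger standard errors. In all, 497 gene probe sets were called in both comparisons, 180 higher in both, 206 lower in both, 58 higher at pH 5.0 and lower at pH 8.7, and 53 the reverse. Independent lists of the same sizes would share 257.9, with 64.3, 64.6, 64.0 and 64.9 in these classes. Simulated unchanged groups gave 0, but they held no changed gene. They therefore cannot show how much the shared pH 7.0 arrays add to the overlap when many genes change. With separate pH 7.0 arrays for each comparison, 184 and 149 were called in both, of which 48 and 31 were higher in both and 95 and 83 lower in both. A further 12 and 23 were higher at pH 5.0 and lower at pH 8.7, and 29 and 12 the reverse. No overlap of independent lists was set beside these counts, and the separate pH 7.0 arrays still shared their scan day and protocol. Across all 4345 gene probe sets, which are not independent, the log2 fold changes had r = 0.406, against 0.495 from the shared arrays alone, and 0.319 and 0.254 with separate pH 7.0 arrays. Their covariance was 0.234, of which sharing gave 0.043. Without the 2 arrays that stood apart 474 were called in both.

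**Figure D3:**
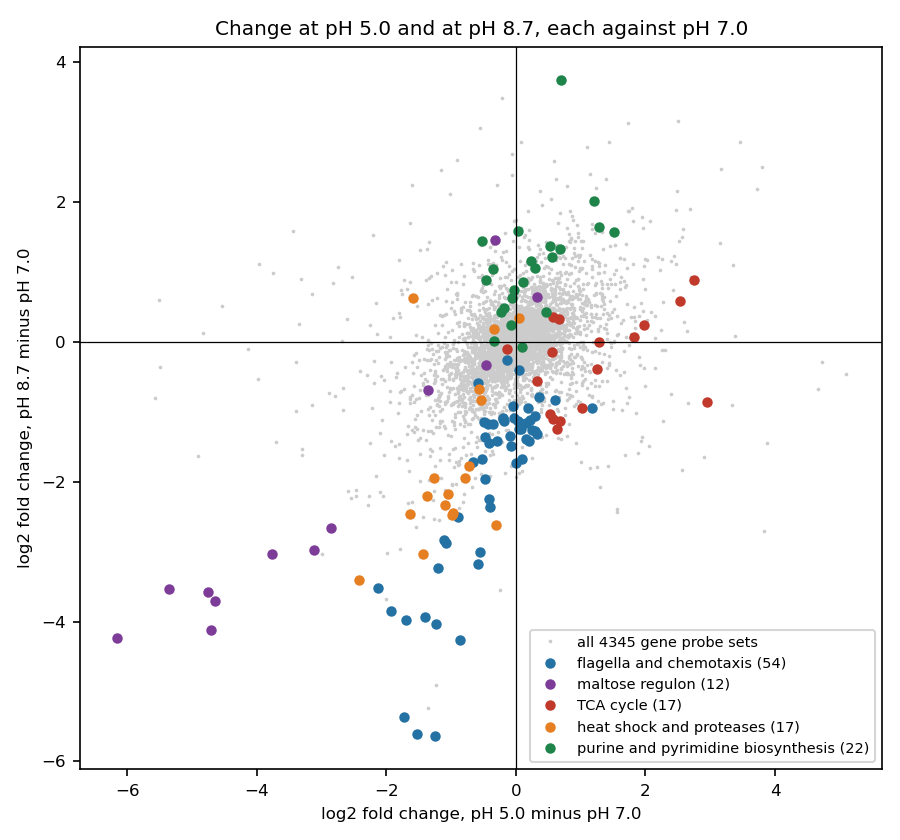
Log2 fold change of each of 4345 gene probe sets at pH 5.0 (x axis) and at pH 8.7 (y axis), both against pH 7.0, with grey points for all and colours for flagella (54), maltose (12), TCA cycle (17), heat shock (17) and purine and pyrimidine synthesis (22). Maltose genes lie low on both axes (medians −3.44 and −3.0), and flagellar genes lie low on the y axis (median −1.38) with a median of −0.25 on the x axis.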

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

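The slope test of the fluidics protocol was chosen after its result was seen, as were the tests of scan days for flagella, cytochrome oxidases and RpoS-dependent stress and the ranges leaving out 1 array. The other tests of scan days and those of other splits of the arrays were chosen before. Each value below marks an array far from the other 4 of its pH, which chance gives in about 1 in 20 groups, and 2 of 9 groups of array measures, 12 of 84 of gene lists and 17 of 327 of genes were marked.

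The differences between pH 5.0 and pH 7.0 run parallel to a change of fluidics protocol, so the protocol was weighed against the pH. Within pH 8.7, where both protocols occur, the protocol difference of the 1248 called gene probe sets had a slope of 0.104 on their pH 5.0 minus pH 7.0 difference (0.082 to 0.126 leaving out 1 pH 8.7 array), far below the 1 that a protocol acting as the whole cause would give. A fit with the protocol as a block takes the protocol difference from the same pH 8.7 arrays and is no separate test. In it the standard errors grew by a median factor of 1.72, and 372 of the 1248 stayed called. Between the protocols within pH 8.7 limma called 0 genes, with 800 at an unadjusted p under 0.05, and 62.5% of the called genes had the sign of their pH difference, so a partial share of the protocol stays open, most for the genes whose fold shrank with the block, such as ahpF (1.25 to 0.42) and sodB (0.70 to 0.16). The pH itself stays the open biological explanation.

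Maltose, heat shock, phosphate, iron, cysteine, flagellar, cytochrome oxidase and RpoS-dependent lists were called in the same direction at pH 5.0 and pH 8.7, which could come from the single scan day of all pH 7.0 arrays. With an estimated correlation, camera called only maltose in both comparisons, flagella only at pH 8.7, and the others in neither. For maltose, the list mean shifted by −3.10 and −2.23 and the largest deviation of any of 7 day means within pH 5.0 or pH 8.7 was 0.17. The ratio of the smaller shift to it was 12.78 (6.92 to 20.79 leaving out 1 array), which argues against a day effect of the size seen elsewhere. For phosphate (−0.91 and −0.95 against 0.05, ratio 17.1) and flagella (−0.39 and −1.97 against 0.12, ratio 3.36) the ratio lay above the limit of 3 but fell to 2.57 and 2.39 without 1 array. For heat shock (−1.0 and −1.72 against 0.53, ratio 1.9), iron (−1.29 and −0.50 against 0.41, ratio 1.24), cysteine (0.60 and 0.83 against 0.59, ratio 1.01), cytochrome oxidases (0.48 and 0.40 against 0.27, ratio 1.47) and RpoS-dependent stress (0.72 and 0.33 against 0.16, ratio 2.04), single days deviated by a comparable amount. For every list but phosphate the largest deviation came from a day with 1 array, so it may belong to that culture or array and not to the day. Day means of phosphate hid a wider spread, with pH 8.7 replicates 1 and 5, of the same day, at mean log2 signals of 7.98 and 8.77. Since no day held 2 pH values, a day effect and the pH cannot be told apart for any of the lists. The deviations come from days within pH 5.0 and pH 8.7, so the effect of the pH 7.0 day itself was not measured. For maltose that effect would have to be far larger than any of these deviations. A response to leaving neutral pH stays open for all 8 lists, untested beyond this, and not always as a shared move of the same genes. For cytochrome oxidases, the 5 cytochrome bo genes rose at pH 5.0, where cydA was at −0.43. At pH 8.7, cydA and cydB of cytochrome bd rose. Between pH 8.7 and pH 5.0, 4 of the 11 genes were higher and 5 lower. RpoS-dependent stress had 3 of 23 higher and 4 lower in that comparison. Against pH 7.0, 27 middle flagellar genes had means of 0.07 at pH 5.0 and −1.18 at pH 8.7, and 16 late ones −1.23 and −3.55.

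The real grouping was the 1 of 100 splits of the arrays with a count as large, for each result, which argues against an arbitrary grouping as the source. The splits treat the arrays as exchangeable, so they do not separate pH from scan day or protocol. Splits that mix pH values also carry the pH difference in their spread, which lowers their counts. The real counts were 1673 among the 3 pH values, 1248, 898 and 1132, and the highest of the other splits gave 19, 24, 31 and 30.

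At pH 5.0 replicate 1 the median deposited signal was 198, against 276 to 297 on the other pH 5.0 arrays, with tnaA at 429 (others 576 to 642), rpsA at 34788 (others 23769 to 26487) and, below background with the others at or next to the imposed floor, gadA at 31.9 (others 10.1 to 10.2). At pH 7.0 replicate 2 the median correlation with arrays of its pH was 0.934, against 0.968 to 0.971. The same array had amino acid-dependent acid resistance at a mean log2 signal of 6.17 (others 5.63 to 5.77), cysteine genes at 7.57 (others 8.13 to 8.29), pdeH at a signal of 6442 (others 3655 to 4090), sufB at 1372 (others 1510 to 1564), and below background cysN at 16.4 (others 33.4 to 41.5) and hyaA at 173 (others 33.1 to 45.5). At pH 5.0 replicate 4, heat shock genes had a mean log2 signal of 11.99 (others 11.30 to 11.36) and cysteine genes 8.10 (others 8.73 to 8.90). On that array htpG was at a signal of 2791 (others 1061 to 1395), pstS at 1359 (others 771 to 827), cheW at 2002 (others 1423 to 1571), cysN at 112 (others 412 to 566) and tsuA at 98.4 (others 1279 to 1744). All pH 7.0 arrays of tsuA lay below background, so its fold has only a bound, and without this array its adjusted p between pH 5.0 and pH 7.0 went from 0.00205 to 3.83e-06.

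The arrays pH 5.0 replicate 5 and pH 7.0 replicates 1 and 5 stood apart in single lists. At pH 5.0 replicate 5 the mean log2 signal was 13.27 for ATP synthase (others 13.12 to 13.16), 9.33 for anaerobic respiration and fermentation (others 9.06 to 9.08) and 7.72 for colanic acid (others 7.26 to 7.39), and gcd was at a signal of 1311 (others 1983 to 2262). At pH 7.0 replicate 1 the acid fitness island was at 6.64 (others 6.52 to 6.53) and outer membrane proteins at 10.93 (others 10.67 to 10.74), and at pH 7.0 replicate 5 purine and pyrimidine synthesis was at 9.26 (others 9.41 to 9.47). At pH 7.0 replicate 4 the signal of flhD was 3949 (others 4832 to 5048) and that of htpG 2280 (others 4238 to 4419). Within pH 8.7, iron genes were at 9.0 on replicate 5 (others 9.73 to 10.0) and drug efflux genes at 8.83 on replicate 2 (others 8.63 to 8.67), and below background flxA was at a signal of 24.9 on replicate 4 (others 103 to 127) and gadA at 31.3 on replicate 3, where the others sat at the imposed floor (10.1).

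Intergenic probe sets, which the comparisons of genes do not use, carried signal as well: 713 of 2886 (24.7%) differed among the 3 pH values by limma, with 1071 at an unadjusted p under 0.05. Of the 59 phage and plasmid probe sets, 1 differed, with 14 at an unadjusted p under 0.05, more than chance gives at that threshold. The background sets may therefore differ between the pH groups too, which overlap with batches.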

How the results depend on the processing

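Fits within 1 protocol or chip lot, the filter at background and the fit without the 2 arrays that stood apart were added after the data were seen. The called counts of genes stayed within 1.5 times their value with the deposited scaling (1121, 810 and 1051 for pH 5.0 against 7.0, pH 8.7 against 7.0 and pH 8.7 against 5.0), median centring (1064, 741, 948), rank-invariant scaling (1249, 904, 1141), both floors, filters on dim probe sets, no variance trend, a chip lot block (1174, 760, 1143) and fits of 2 pH values alone (1434, 720, 1076). None of the called genes changed sign with the 3 scalings or without a floor, and with the floor at the 25th percentile 1 did, pgaC for pH 8.7 against 5.0, which was dim at both and is named after its values were seen. Calls of single genes and lists were less stable than the counts. Counting each comparison of a named gene, 12 calls were lost with the deposited scaling, 16 with median centring and 14 with the floor at the 25th percentile, among them tnaA for pH 8.7 against 7.0 (adjusted p = 0.121, 0.0731 and 0.0505). Of lists, colanic acid for pH 8.7 against 7.0 lost its call with rank-invariant scaling (0.0533), no floor (0.051), the higher floor (0.149), both filters (0.59 and 0.804), array weights (0.0617) and fits of 2 pH values (0.0631). For pH 8.7 against 5.0 it lost it with both filters (0.184 and 0.525). The cysteine list for pH 5.0 against 7.0 lost its call with the higher floor (0.0588), the filter at background (0.0609), array weights (0.0937) and fits of 2 pH values (0.0719). The acid lists for pH 8.7 against 5.0 lost theirs with the higher floor (0.125 and 0.0541), and amino acid-dependent acid resistance with the filter at the intergenic median (0.154, and 0.0651 for pH 5.0 against 7.0). Sugars for pH 5.0 against 7.0 were lost with the filter at background (0.0931) and array weights (0.0504), and RpoS-dependent stress for pH 8.7 against 7.0 with that filter (0.144). Outer membrane proteins for pH 5.0 against 7.0 gained a call with the deposited scaling (0.0194), median centring (0.0139), no floor (0.0455) and the filter at the intergenic median (0.0365). For pH 8.7 against 5.0, calls were gained by outer membrane proteins with the deposited scaling (0.0276) and median centring (0.0172), by ribosomal proteins with the same (4.56e-06 and 3.98e-04), and by arginine and envelope stress with median centring (0.0341 and 0.0362), arginine also with the filter at background (0.0241). Array weights raised pH 5.0 against 7.0 to 1925 and intergenic calls to 1076, and the cause was not tested. With the protocol block pH 5.0 against 7.0 gave 514 and both comparisons 252, with larger standard errors, sodA reversed (0.41 to −0.059) and sufC reversed (−0.79 to 0.23), the cause of both not tested. With the scan day as a random block, the counts were 736 and 514 against pH 7.0, 224 in both and 416 intergenic, and camera was not run with that block. Numbers of replicates do not pair the arrays (median r of deviations −0.061 for the same number), and as a replicate block they gave 1093, 790 and 1026, with 1066, 770 and 1002 of the calls kept.

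Stricter thresholds gave fewer calls by construction, and fits within 1 protocol or chip lot gave fewer as well. At an adjusted p under 0.001 there were 644 among the 3, 348, 283 and 483 between pairs, 260 and 224 of at least 2-fold against pH 7.0, 93 in both and 180 intergenic. The authors' test at 0.001 on these values gave 811 among the 3, 423, 355 and 518 between pairs, 277 and 238 of at least 2-fold against pH 7.0, and 123 in both. Within the earlier protocol pH 8.7 against 7.0 gave 595. Chip lot 1 alone gave 627 among the 3, 528, 250 and 360, with 222 (pH 8.7 against 7.0) and 313 (pH 8.7 against 5.0) of at least 2-fold, 118 in both and 168 intergenic. Chip lot 2 alone gave 787, with 238 and 220 against pH 7.0, 209 and 201 of at least 2-fold, 85 in both and 295 intergenic. Splitting the pH 7.0 arrays gave 184 and 149 in both. Camera with an estimated correlation left 8 of the 40 list calls. Correlation among the members does not explain every loss. Amino acid-dependent acid resistance lost its calls with an estimated correlation of −0.001, under the preset 0.01. With fry, which tests members without setting them against other genes, 22, 15 and 20 lists were called for pH 5.0 against 7.0, pH 8.7 against 7.0 and pH 8.7 against 5.0, where camera called 15, 13 and 12. Ribosomal proteins for pH 8.7 against 7.0 were the only list lost (0.0779). Those gained were 7, 3 and 8, among them envelope stress and outer membrane proteins in all 3 comparisons.

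Leaving out 1 array at a time gave 1432 to 1775 among the 3, 996 to 1358 for pH 5.0 against 7.0, 723 to 907 for pH 8.7 against 7.0 and 972 to 1206 for pH 8.7 against 5.0. At least 2-fold, these were 434 to 566, 347 to 407 and 505 to 564. In both comparisons there were 358 to 527, intergenic 545 to 792 and lists 37 to 44. For 1570 gene probe sets the mean lay below background at every pH, which limits what can be said of acid resistance, hydrogenase and capsule genes.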

Other observations

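The tests of neighbouring genes, of flagellar classes and of the protocol in tRNA genes were chosen after the results were seen, that of shared tRNA copies before, and the operons and the RNA named here were picked after their values were seen. Genes next to each other on the chromosome changed together by at least 2-fold in 44 runs of 4 or more over the 3 comparisons (15 for pH 5.0 against 7.0, 13 for pH 8.7 against 7.0 and 16 for pH 8.7 against 5.0), where 1000 shuffled orders of the 4230 placed genes gave at most 3. At pH 5.0 against pH 7.0 the pyruvate dehydrogenase run pdhR, aceE, aceF and lpd was higher (median log2 fold change 1.85, range 1.40 to 2.27, and 1.48 with the protocol as a block). The run of nrdG, nrdD, treC and treB was lower (−2.50, or −2.59 with the block). The type 1 fimbriae genes fimA to fimH, 7 in a row, were higher (1.64, or 0.38 with dim members at their bound). At pH 8.7 against pH 7.0, nucleoside breakdown genes deoC, deoA, deoB and deoD were lower (−2.33), as were srlA, srlE, srlB, srlD and gutM for sorbitol (−2.07). The run from wbbL to rfbC, 8 genes for the O antigen, was higher (1.31). Between pH 8.7 and pH 5.0, 7 galactitol genes from gatR to gatY were lower at pH 8.7 (−1.61). Shared transcription of neighbours is a candidate explanation of the 44 runs, and operon structure itself was not tested.

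Among intergenic probe sets, csrB, a small RNA that binds the regulator CsrA, had a signal of 921.8 ± 259 at pH 5.0, 3989 ± 452 at pH 7.0 and 7897 ± 3260 at pH 8.7 (SD, n = 5 each). It was lower at pH 5.0 than at pH 7.0 (log2 fold change −2.15, SE 0.29, limma adjusted p = 1.77e-04) and not called between pH 8.7 and pH 7.0 (0.87, adjusted p = 0.0672).

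A hypothesis on the flagellar genes is that the fall follows the order of the transcription cascade, in which late genes depend on fliA. At pH 8.7 against pH 7.0, 16 late genes had a mean log2 fold change of −3.55 (SD 1.39) and 27 middle genes −1.18 (SD 0.21), a difference of −2.36 with a 2-sided permutation p of 1e-05, the smallest that 100000 resamples can give. At pH 5.0 the means were −1.23 (SD 0.49) and 0.07 (SD 0.35), a difference of −1.30. At pH 8.7 late genes, middle genes and fliA all fell, which the cascade allows. At pH 5.0 the late genes fell, while the middle genes as a group did not and fliA (−0.2) was not called. The fall of late genes there came without a called fall of the fliA transcript, so the hypothesis is not borne out at pH 5.0. The limits are that genes of an operon are not independent and that floors on dim signals shrink the late values.

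Of 79 tRNA probe sets, 12 were higher and 8 lower at pH 5.0 than at pH 7.0, with a median log2 difference of 0.16. A protocol effect could give such a shift: within pH 8.7 the later protocol was higher by a median of 0.32, 2.015 times the pH difference (0.725 to 3.085 leaving out 1 array), but members went both ways, so protocol and pH cannot be told apart. Probes shared between gene copies were the other explanation. The 18 unshared sets had a median of 0.53 and the 61 shared ones 0.13, a ratio of 4.071, above the 0.5 set beforehand to count against it, yet that bound assumed that members move one way, and with 5 higher and 4 lower among the unshared the medians decide nothing.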
